A study of Mus musculus with 2 samples.

How the data were processed

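Cells of pooled embryonic mouse lungs were dissociated with dispase, per the labels' protocols, and loaded on a 10x Genomics Chromium controller with a kit that captures the 3′ end of polyadenylated transcripts. A library of 6 control lungs and a library of 7 mutant lungs, both at E12.5, were sequenced. Per the submitters' processing notes, Cell Ranger 3.0.2 and Seurat 3 were used, with genome build mm10. The role of each tool, the annotation release, the handling of strand and any filter are not given in the sources used here.

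The deposited files used here are the barcode list and the feature list of the unfiltered matrix of each library. They hold names and no measured values. A barcode list gives the barcode of every matrix column, and a feature list gives the gene identifier, symbol and feature type of every matrix row. The count matrices were not analysed here, so UMI counts, depth per library and per cell, filters on cells, doublets, clusters and cell types could not be examined. Analyses of expression had been set out for the case that counts could be analysed, and none was run.

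Samples were grouped by the genotype in their labels. With 1 library per group no test between genotypes was made, and no n, SD or p-value is given for any difference between them. Intervals of shares are exact Clopper-Pearson binomial intervals at 95%, and intervals of ratios of shares are 95% normal intervals on the log scale. They and all SDs of expected overlaps cover counting error within these libraries only. The intervals treat barcodes as independent draws, although use differed between segments of one class. Rarely used trailing segments of the control had 15 to 116 barcodes (5th to 95th percentile), so the intervals may be too narrow.

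Feature lists were compared line by line and matched by identifier to the primary assembly annotation of GENCODE M21, on GRCm38. Of 31053 identifiers, 31011 were found there. Coordinates are 1-based and from that annotation. Gene lists and cell type markers were fixed before the data were examined and matched by exact symbol. The rule for named genes, fixed then as well, was to name Srf and members of these lists only by whether they were features where counts are not analysed. The overlapping features Gm26904, Gm20388 and Uxt fall outside the rule and are named as neighbours of listed genes.

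Barcodes were reduced to their 16 bases, coded as integers and compared exactly. The pool was built as all joins of the leading and trailing segments of 8 bases seen in either list that keep the pairing between positions 8 and 9. The overlap of independent draws was computed from the hypergeometric distribution, first over the whole pool, then within each trailing segment. A further model kept the rates of both segments with multiplicative odds. Trailing segments were divided at the emptiest bin, of width 50, between the peaks of their total number of barcodes. Neighbours were sought among all 48 sequences at 1 mismatch. The segments, their classes, the pool and the analyses built on them were chosen after seeing the data. The planned analyses were the number of barcodes, their overlap, base composition, one-mismatch neighbours and the features.

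The overlap and neighbour functions were tested on simulated data, as lists drawn from the real pool of 6794880 barcodes. With no exchange between the lists, the overlap over that expected at the trailing segments' rates was 1.00. With 2% of barcodes exchanged it was 1.01. All simulated segments were assigned to their true class, which was bound to happen because every segment of a class had the same simulated rate. Leading segments did not differ in rate either. With simulated read errors, the ratio of listing shares used for one-mismatch partners was 2.42 (95% interval 2.27 to 2.57), and without them 1.04 (0.966 to 1.12). The simulated rates were not fitted to the lists, so the size of these ratios cannot be compared with the observed ones.

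Alternatives tried were unique sequences in place of lines, leaving out barcodes with runs of 5 or more equal bases, thinning the longer list, leaving out barcodes with one-mismatch neighbours, overlap by starting base, barcodes of one library only, neighbours in the union of both lists, and symbols in any letter case or by synonym. Computation used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and the plots used matplotlib 3.10.9.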

Results

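Lungs of mouse embryos were collected at E12.5, the embryonic stage, and profiled by droplet single-cell RNA sequencing. The control library held pooled cells of 6 lungs homozygous for a floxed Srf allele. The mutant library held pooled cells of 7 lungs that also carried Tbx4-rtTA and tet-O-Cre, a doxycycline-dependent Cre system driven from Tbx4 regulatory sequence, which is active in lung mesenchyme. SRF, serum response factor, is a transcription factor that binds CArG elements of contractile and immediate early genes. From the title of the series, the comparison addresses how airway smooth muscle forms in the developing lung when Srf is removed from the mesenchyme. Each genotype was represented by 1 library, so no spread between lungs or between libraries could be estimated, and no test between genotypes was possible.

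What could be compared here were the gene features and the cell barcodes that label the rows and columns of the unfiltered count matrix of each library. The counts themselves were not analysed here. No expression value, cell number, cell type share or sequencing depth is therefore given for either genotype. The question of what happens to airway smooth muscle was not addressed by these lists.

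Both libraries were annotated with the same genes. Srf was a feature in both (ENSMUSG00000015605), as were Tbx4 (ENSMUSG00000000094), a T-box transcription factor of lung mesenchyme, and Acta2 (ENSMUSG00000035783), which encodes smooth muscle α-actin. Each list held 31053 genes, and 0 lines differed between them in identifier, symbol or order. Cre and rtTA were not features, so transcripts of the transgenes had no row of their own in either library.

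In GENCODE M21, on GRCm38, the assembly that mm10 also names, Srf lies on the minus strand of chromosome 17 from 46548329 to 46556175. Its longest coding transcript has 7 exons. Exon 1, with the start of the transcript, spans 46555328 to 46556175, and exon 7, the last one, spans 46548329 to 46549178. The labels do not state which exons are flanked by loxP sites. Srf counts from a kit that captures the 3′ end come mainly from the last exon. They would check the deletion only if it removed that part of the transcript or lowered its amount. Gm26904, another feature, overlaps Srf on the opposite strand.

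The smooth muscle genes fixed for the comparison were all among the features. All 10 contractile genes fixed as SRF targets were features, among them Acta2 on chromosome 19 (34241090 to 34255590), Myh11, smooth muscle myosin heavy chain, on chromosome 16 (14194535 to 14291372), Tagln, transgelin, on chromosome 9 (45929619 to 45936058) and Cnn1, calponin 1, on chromosome 9 (22099216 to 22109630). All 10 actin cytoskeleton genes of the SRF program, such as Vcl, which encodes vinculin, and Flna, which encodes filamin A, were features as well. The list of immediate early genes held 10 symbols for 8 genes, and all 8 genes were features, including Egr1 and Fos. Ccn1 and Ccn2 are newer symbols of Cyr61 and Ctgf, under which these genes stood. The list of SRF and its cofactors held 9 symbols for 7 genes, and all 7 genes were features, including Myocd, the myocardin coactivator of smooth muscle genes. Mrtfa and Mrtfb are newer symbols of Mkl1 and Mkl2, under which these genes stood.

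Markers of the other cell types fixed for the comparison were also features. A feature list names genes that could be counted and does not show whether they were expressed in these lungs. All 10 smooth muscle markers and all 10 markers of undifferentiated mesenchyme, such as Tcf21 and Fgf10, were among the features. So were the 5 markers of sub-epithelial mesenchyme, with Lef1 and Ptch1, and the 5 of pericytes, with Pdgfrb. The 9 epithelial markers included Nkx2-1 and Sox9, and the 5 endothelial markers included Pecam1. The lists for mesothelium (5 genes), immune cells (5), erythroid cells (8), neural crest and neurons (6), cardiac muscle (5), skeletal muscle (3) and cartilage (4) were complete as well. The same held for the lists of lung signalling genes (15, with Wnt2, Shh and Bmp4), extracellular matrix (10, with Eln and Fn1), proliferation (6) and handling stress (5). Over all 22 lists, 134 of 140 symbols were found as written. Of the 6 not found, 4 are the newer symbols of Cyr61, Ctgf, Mkl1 and Mkl2, which are already among the 134, and the others are Cre and rtTA.

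Of the 134 genes found, 42 share sequence positions with another feature on either strand. Elk1, Foxf1, Cx3cr1 and Tubb3 were the 4 listed genes whose span overlaps another feature on the same strand. Foxf1, a forkhead factor of lung mesenchyme, and Tubb3, a neuronal tubulin, both overlap the long locus Gm20388 on chromosome 8. Elk1, an SRF cofactor on chromosome X, overlaps Uxt. On the opposite strand, 39 symbols overlap a feature, among them Srf, Tagln, Des and again Cx3cr1. These overlaps are of whole gene spans and not of exons. How strand was used in counting is not given in the sources used here. Whether counts of these genes would mix with those of their partners is therefore not known. Protein-coding genes made up 21974 of the 31053 features, lincRNAs 5459 and antisense transcripts 2816.

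The number of barcodes was slightly higher in the control library. The control list held 2397358 barcodes and the mutant list 2296922, a ratio of 0.958 for mutant over control. These are barcodes of the unfiltered matrix and not cells. With 1 library per genotype the difference of 100436 barcodes has no replicate check.

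The barcodes of both libraries had one common structure. Every barcode had 16 bases and the same suffix, and none occurred more than once in a list. The base at position 8, counted from 1 at the 5′ end, fixed the base at position 9, and 4 of the 16 possible base pairs occurred at these positions. Cut between these positions, the barcodes of each library used the same number of segments of 8 bases, 3840 leading and 7078 trailing. All joins of a leading and a trailing segment that keep the pairing number 6794880, and this set is called the pool here. The kit's own list of possible barcodes was not compared here. Nothing in this structure is therefore read as a property of the lungs or genotypes. The control library listed 35.28% of the pool (exact 95% binomial interval 35.25% to 35.32%) and the mutant library 33.80% (33.77% to 33.84%). These intervals cover counting error only.

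Trailing segments fell into a commonly used and a rarely used class in both libraries. In the control library a commonly used segment occurred in a median of 575 listed barcodes and a rarely used one in 51, of 960 possible. In the mutant library the medians were 549 and 51. The total of both libraries that separated the classes was 525 barcodes, and 20 of the 7078 segments lay within 100 of it. The 3856 commonly used segments accounted for 92.3% of the control list and 92.0% of the mutant list. Of the pool members with a commonly used segment, 59.8% were listed in the control and 57.1% in the mutant. For the 3222 rarely used segments these shares were 5.95% and 5.93%. Leading segments showed no such division, with a median of 624 listed barcodes in the control (5th to 95th percentile 548 to 708) and 597 in the mutant (515 to 689).

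**Figure D1:**
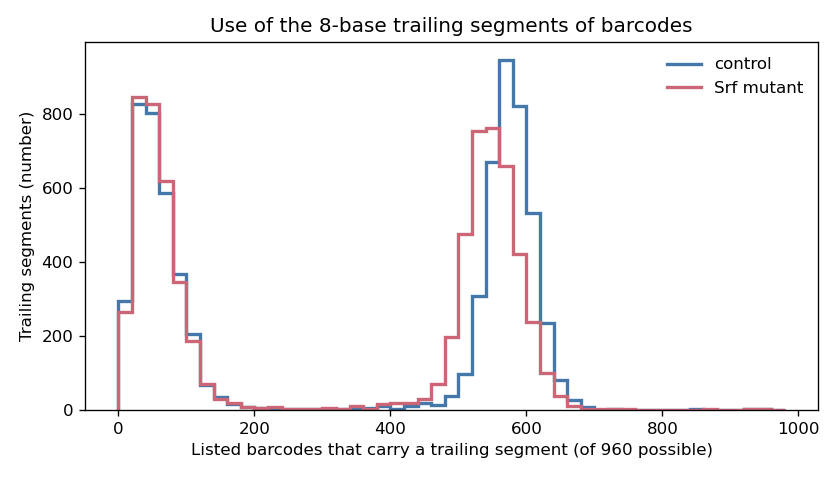
Number of trailing segments (y axis) by the number of listed barcodes that carry them (x axis, bins of 20 barcodes, of 960 possible), with 1 outline per library. Both libraries show a peak around a median of 51 barcodes, and another around medians of 575 in the control and 549 in the mutant.

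More barcodes were shared between the libraries than independent draws from the pool give. The lists had 1307919 barcodes in common, which is 54.6% of the control list and 56.9% of the mutant list. Independent draws of these sizes from the pool would share 810396 (SD 589), so the observed number was 1.61 times as large. When each trailing segment kept its own rate in each library, the expected overlap was 1284501 (SD 476) and the ratio 1.02. Split by class at these rates, the ratio was 1.01 for commonly used segments (1285572 shared, 1270082 expected, SD 463) and 1.55 for rarely used ones (22347 shared, 14419 expected, SD 108). With the rates of both segments kept, it was 1292725 (SD 471) and the ratio 1.01, which still left an excess of 15194 barcodes, or 32.3 SD. With 1307919 barcodes in both unfiltered lists, a listed barcode alone does not always tell which library it came from. How many barcodes of cells were shared was not examined.

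Base composition was nearly equal between the libraries. Over all positions and bases the shares ran from 23.0% to 28.5%. The largest difference was for A at position 8 and, through the pairing, equally for G at position 9, with 25.2% in the control and 24.8% in the mutant, a difference of 0.39 percentage points. Its counting error of 0.040 percentage points treats the lists as independent, although they share 1307919 barcodes. The spread between libraries of one genotype is unknown.

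Barcodes that differ from another listed barcode by 1 mismatch made up nearly equal shares of both lists. They were 11.1% of the control list and 11.1% of the mutant list. Random sequences of the same number would give 2.64% and 2.54%. Draws from the pool at each trailing segment's own rate gave 10.7% and 10.5%. Among barcodes with a rarely used trailing segment the share was 58.0% in the control and 56.0% in the mutant, against 7.20% in both for those with a commonly used one.

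The listing of barcodes with a rarely used trailing segment was more frequent the more of their commonly used one-mismatch partners were listed in the same library. For barcodes with 3 such partners in the pool, 3.35% were listed in the control when none of the partners was (exact 95% interval 3.11% to 3.60%). The share was 6.69% with 1 partner listed, 9.89% with 2 and 13.1% with 3 (12.8% to 13.3%). In the mutant the shares were 3.38%, 6.51%, 9.73% and 13.3%.

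**Figure D2:**
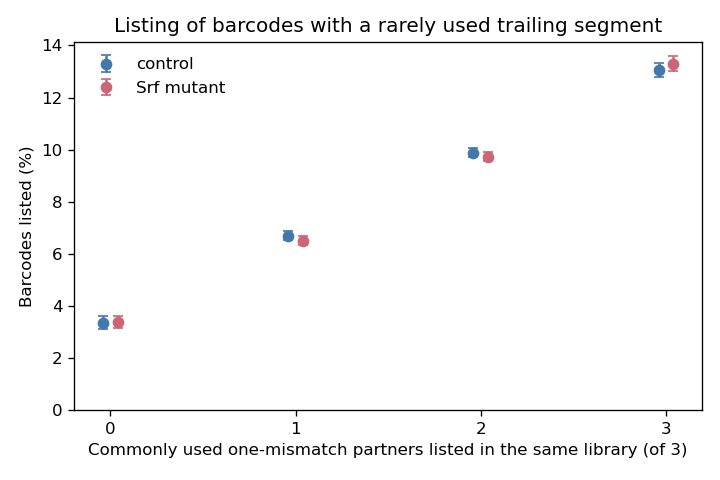
Share of pool barcodes with a rarely used trailing segment that were listed (y axis, percent) by how many of their 3 commonly used one-mismatch partners were listed in the same library (x axis). Points are the 2 libraries, bars are exact 95% binomial intervals, and the share goes from 3.35% to 13.1% in the control and from 3.38% to 13.3% in the mutant.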

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

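The number of barcodes and of features did not change under any alternative run, but leaving out runs of 5 or more equal bases removed 0 barcodes and so tested nothing. The overlap of 1307919 barcodes became 1253072 with the control list thinned to the length of the mutant list, and 1131234 without barcodes that have a one-mismatch neighbour in their own list. The ratio of the observed overlap to that of independent draws, 1.61, was 1.77 without barcodes that have such a neighbour. The 1.77 was computed with the full pool. Barcodes with a rarely used trailing segment had such a neighbour more often (58.0% in the control and 56.0% in the mutant, against 7.20%). The 1.77 therefore cannot be compared directly with 1.61. The ratio was 1.63, 1.61, 1.62 and 1.601 for barcodes starting with A, C, G and T. It fell to 1.02 at the trailing segments' own rates (1.012 within the commonly used class, 1.55 within the rarely used class) and 1.01 at both segments' rates, alternatives added after seeing the data. The largest difference in base composition, 0.39 percentage points, was 0.73 in barcodes of one library only, which leave out the sequences both lists hold. The share of barcodes with a one-mismatch neighbour, 11.1% in both libraries, was 15.96% in the control and 16.1% in the mutant when neighbours were sought in the longer union of both lists. The rarely used class of 3222 segments held 3134 and 3674 when split at 1/2 of the dividing total and at 2 times that total. Of the fixed symbols, 134 were found in any letter case and 138 with synonyms, of which 4 name genes already counted under their older symbol. Other cell filters, mitochondrial limits, cluster resolutions and scalings, set before the data were examined, were not run, since they need counts. No paired analysis was possible because each group had 1 library. Depth could not be assessed, because the lists give no number of molecules.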

Other observations

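Tests of the overlap at the segments' own rates and of adapter-like endings were chosen only after the results were seen; the tests on one-mismatch partners in the same or the other library were set before their values were computed. No biological explanation was tested for any of these patterns, because genotype and library coincide.

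The libraries shared 1.61 times as many barcodes as independent draws from the pool give. Unequal use of trailing segments may account for most of this, since the ratio fell to 1.02 once each segment kept its own rate, but that value is set mainly by commonly used segments, whose ratio was 1.01. As the whole cause among rarely used ones it is argued against, because at the same rates their ratio was 1.55, an excess of 7928 barcodes or 73.2 SD, against 15490 barcodes for commonly used segments. What raised the overlap of rarely used segments was not tested. Exchange of reads between the libraries as the whole cause is argued against, because exchange would leave most of the excess within trailing segments and 4.71% of it was left there. Whether exchange contributed to what remained at both segments' rates, a ratio of 1.01, cannot be told apart from single barcodes being more abundant on the beads of both libraries, since the lists hold no counts per barcode.

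Barcodes with a rarely used trailing segment were listed at 5.95% and 5.93% of their pool in the control and the mutant. If these were read errors of abundant barcodes, their listing should follow partners in the same library. For those with 1 partner in the pool, listing was 1.56 times as frequent in the control when that partner was listed in the control alone (7.00%) as when it was listed in the mutant alone (4.49%), with a 95% interval of 1.51 to 1.61. In the mutant the ratio was 1.63 (1.58 to 1.68), so single-base read errors may account for part of these barcodes. Families of barcodes abundant in both libraries may add a smaller part. For a partner listed only in the other library against one listed in neither, the ratios were 1.08 (1.04 to 1.12) and 1.06 (1.03 to 1.10). Neither comparison can separate these explanations from unequal use of leading segments. A rarely used barcode and its commonly used partner carry the same leading segment, since their trailing segments differ. Leading segments differed in use, with a Pearson correlation of 0.797 between the libraries, and their rates were not kept here. The 4.16% and 4.14% listed with the partner in neither stay unexplained.

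A few trailing segments were listed with nearly every leading segment they can join. GCTGGCTC stood in 959 control and 958 mutant barcodes of 960 possible, and CCTGGCTC in 956 and 960. All 4 trailing segments that end in CTGTCT, the first 6 bases of the reverse complement of the Tn5 transposase mosaic end, stood in 845 to 947 control and 868 to 957 mutant barcodes, and this ending had rank 1 of the 1044 endings of 6 bases found on more than 1 commonly used segment, by median number of barcodes. GCTGGCTC and CCTGGCTC, ranks 1 and 2 of all 7078 trailing segments, are the 2 segments of the pool whose last 7 bases are within 1 mismatch of the adapter's first 7, and 0 segments match those 7 exactly. An exact comparison, made first, matched 1 base at their ends and allowed for no read error or barcode correction. The ending CTGTC, the adapter's first 5 bases, gave mixed values: CACCTGTC (905 control and 901 mutant barcodes), GACCTGTC (848 and 862) and ATCCTGTC (758 and 748) ranked 6, 8 and 9, whereas TTCCTGTC (606 and 623) and GTACTGTC (592 and 600) were closer to the medians of 575 and 549, and CTACTGTC (151 and 149) was rarely used. The 2 segments within 1 mismatch of the adapter's first 8 bases, CTGTCGCT (557 and 582) and CTGTCTCG (549 and 553), did not stand out. The labels name a kit spelled Nextra, read here as Nextera, which uses that transposase. The comparisons at 5, 6 and 7 bases were prompted by these segments and decide nothing about the adapter, so matches that had not prompted them were compared. Counts of such matches among the 10 most listed segments, tried first, were dropped, since so short a list could not hold most of them. Of the 101 commonly used segments that end in exactly the adapter's first 3 or 4 bases, 18.8% (95% interval 11.7% to 27.8%) were among the 5% most listed. This is above 5% but not a majority, a bound that was itself written after results had been seen. How often each length of adapter is read is unknown. Transposase adapter read in place of the barcode's end therefore stays open. Of the 93 commonly used segments with 1 mismatch to its first 5, 6 or 8 bases, 5.38% (1.77% to 12.1%) were among the 5% most listed, so the source of the 2 most listed segments stays open as well.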
